A study of Mus musculus with 11 samples.

How the data were processed

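Chromatin accessibility was measured by ATAC-seq (an assay in which a transposase cuts and tags open DNA) in 11 libraries of mouse CD8 T cells that carry a YFP reporter at Tcf7, per the labels. The libraries fall into 6 groups. Naive cells (CD44-negative, CD62L-positive, YFP-positive splenocytes), antigen-experienced cells (CD44-positive, CD62L-positive, YFP-positive splenocytes) and effector cells activated for 3 days in culture had 1 library each. The other 8 libraries came from cells sorted by YFP at day 3, cultured again and sorted at day 9. They were high at both sorts (high_to_high, 2 libraries), low at both sorts (low_to_low, 3 libraries), or low at day 3 and high at day 9 (low_to_high, 3 libraries). The labels do not say whether replicates came from separate animals or cultures, so the p-values may measure only the spread between preparations.

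The deposited files are peak lists, called on each library alone without a control and not on pooled replicates. Peaks were called with HOMER 4.10 findPeaks, per the file headers, at a false discovery rate of 0.001, at least 4-fold over the surrounding 10 kb and at a local Poisson p of at most 1e-04. The submitters' processing notes name Bowtie2, HOMER, DESeq2 and build mm10 without saying what DESeq2 was used for. The deposited signal of a peak is its normalized tag count, the tags in the peak window per 10 M (mega) tags of that library, per the file headers. Values under 10 were whole numbers of read ends in every library, within 0.1 of a read end. Over all values, 52.6 to 68.6% were whole, since higher values are rounded in the files. Peak windows were 172 bp wide in 9 libraries, 132 bp in the naive library and 136 bp in high_to_high replicate 2, where the caller had taken a fragment length of 86 bp.

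Total tags ran from 20.8 M (low_to_high replicate 3) to 59.97 M (high_to_high replicate 2), and the lists held 46454 to 66117 peaks. The weakest peak of a list rested on 16 to 28 read ends, so regions below that level are missing from a list and are not known to be closed. The filter on local signal removed 36.4 to 53.3% of the putative peaks of a library. Regions above that level can therefore be missing as well. No binomial intervals are given, since read pairs are not independent single counts and the spread between replicates covers counting error.

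Peaks on autosomes and the X chromosome that overlapped by at least 1 bp were merged across the 11 libraries (checked against bedtools 2.31.1) into 111041 regions. Peaks on the Y chromosome and on unplaced sequence, at most 0.104% of a list, were left out. A region took the value of its strongest peak in each library. Regions were assigned to the protein-coding gene with the nearest span within 100 kb in the RefSeq table of the same build, which gave a gene to 94.4% of regions. The design had named the nearest transcription start, but the table gives no strand, so the distance to the gene span was used. All 164 genes of the 11 gene lists were in the table. Assignment is by distance and does not show which gene a region regulates. The genome sequence was not used here, so the motif tests of the design were not run.

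Differences between day 9 groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(normalized tag count + 1), with each library centred on its median, over the 34383 regions called in all 8 day 9 libraries. Fold changes are on that scale, which understates changes of low values, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. YFP-high against YFP-low used 2 groups of 5 and 3 libraries. The 3 comparisons between pairs of groups came from 1 model of the 3 groups. Gene lists were tested with limma's camera (preset correlation 0.01, lists with at least 5 tested regions), with adjustment over the lists of each comparison. Peak lists were compared by the Jaccard index over regions, and shares of regions by exact permutation tests. The single naive, antigen-experienced and effector libraries have no test. For them, the median difference of a gene list over its regions called in both libraries, centred on the median of all such regions, was ranked among 10000 random sets of as many regions matched on level.

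On simulated values with the spread of the real libraries and 34383 regions, 95.5% of regions changed 2-fold were called for YFP-high against YFP-low, 76.1% for low_to_high against low_to_low, 73.1% for high_to_high against low_to_low and 61.2% for low_to_high against high_to_high. Of regions changed 1.5-fold, 53.7, 38.8, 26.9 and 29.9% were called, in the same order. False calls were 2.05 to 5.30% of calls. A simulated set of 60 regions shifted by 0.3 on the log2 scale was called by camera, and 0 of 9 unshifted sets were. The simulated regions and libraries varied independently. In the data, regions of the naive and memory list had an estimated correlation of 0.0725 for YFP-high against YFP-low, and same-numbered libraries correlated as well. These rates therefore need not hold for the real libraries.

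Whether replicate numbers pair libraries was checked from the correlation of deviations from the group means. Same-numbered low_to_low and low_to_high libraries correlated at 0.298, 0.136 and 0.161, all above those of differently numbered libraries. High_to_high libraries correlated with no number (-0.0407 to 0.0407). The numbers were therefore taken to pair low_to_low and low_to_high libraries, on the data and not on the labels. The fit with the replicate number as a block is given beside a count that it changes. Except in the fit of low_to_high and low_to_low alone, that block also covers the high_to_high libraries, for which the correlations showed no pairing.

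Alternatives were the deposited scale without centring, cyclic loess, a pseudocount of 10, values per kb of peak, leaving out the lowest 25% of values, regions called in at least 3 day 9 libraries with missing values set to the library's lowest, 500 bp windows, the replicate block, other groupings of the libraries in the model, and leaving out each library. The share of tags in peaks as a covariate, limma voom on recovered read ends, a blocked fit of low_to_high and low_to_low alone, the block together with the share of tags in peaks, cyclic loess for the gene lists, and list regions within 1 kb of a gene-span end were added after the data were seen. Peak lists were also compared with equal numbers of strongest peaks, with peaks above the median of their list, by base pairs and with 50% reciprocal overlap. Gene lists were also tested with genes within 20 kb and with an estimated correlation. A count model (DESeq2 and a quasi-likelihood test) was not run, because whole reads could not be recovered for most values above 10.

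The groups, comparisons, gene lists and the rule for named regions were fixed before the data were examined. The rule takes all regions assigned to Tcf7. Per comparison it takes the 10 called regions in each direction with the largest fold change among those whose groups do not overlap, 1 per gene, or the 3 with the lowest p where fewer than 5 were called. It also takes up to 4 called genes of each list, and the 10 regions per direction with the highest mean value among those called in every library of 1 YFP state and in none of the other.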

Results

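ATAC-seq profiled open chromatin in 11 libraries of mouse CD8 T cells with a YFP reporter at Tcf7, the gene of the transcription factor TCF-1, which marks naive and memory T cells. Reference libraries came from naive splenocytes, antigen-experienced splenocytes and effector cells after 3 days of activation in culture, with 1 library each. Cells sorted as YFP-high or YFP-low at day 3 were cultured again and sorted at day 9, which gave 2 libraries that were high at both sorts (high_to_high), 3 that were low at both (low_to_low) and 3 that went from low to high (low_to_high). The design addresses whether cells sorted as low at day 3 and as high at day 9 share the open chromatin of cells that were high at both sorts. Sequencing depth was 37.5 M tags for naive, 23.5 M for antigen-experienced and 53.2 M for effector cells. It was 25.8 and 59.97 M for high_to_high, 40.7, 41.9 and 23.3 M for low_to_low, and 40.5, 27.7 and 20.8 M for low_to_high replicates. The share of tags inside peaks was 9.01 to 10.2% in the 5 YFP-high libraries of day 9 and 10.4 to 12.5% in the 3 YFP-low libraries, so that the YFP states did not overlap in it. The lists merged into 111041 regions, of which 34383 were called in all 8 day 9 libraries and 23471 in all 11.

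The day 3 effector library held the most distinct set of open regions among the 3 references. It shared 32333 regions with the naive library, added 33711 and lacked 25065, a Jaccard index (shared regions over all regions of a pair) of 0.355. Antigen-experienced and naive cells shared 44068 regions, with a Jaccard index of 0.694. Regions assigned to 28 effector genes such as granzymes, Ifng and Tbx21 had a median log2 value 0.61 higher in effector than in naive cells, relative to the median region called in both, above all 10000 random sets of regions of like level, and regions of 20 genes of interleukin-2 signalling and activation were 0.46 higher, also above all of them. In antigen-experienced cells the same lists were 0.24 and 0.15 higher than in naive cells, at the 100th and 99.9th percentile of random sets. Marker lists of other cells moved as far between these 2 libraries, with 0.29 for B cells (97.3rd percentile), 0.17 for natural killer cells (96.5th percentile) and -0.24 for CD4 and regulatory T cells (below the 1st percentile). Regions of 24 naive and memory genes were 0.11 lower in effector than in naive cells, at the 40.6th percentile, and 0.22 lower than in antigen-experienced cells, at the 1.48th percentile. Regions of the B cell marker list were 0.87 higher in effector than in naive cells (97.7th percentile), and those of the myeloid list 0.40 higher (95.7th percentile). Each reference is a single library, so these differences have no replicate check, and the random sets draw regions singly and not by gene.

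The Tcf7 locus (chromosome 11, 52246527 to 52283383, mm10) carried 17 regions, 8 of them inside the gene and 4 called in all 8 day 9 libraries. The region starting at 52265656, inside the gene, held a normalized tag count of 57.4 ± 10.7 in high_to_high (SD, n = 2), 55.6 ± 5.22 in low_to_high (n = 3) and 67.8 ± 7.51 in low_to_low libraries (n = 3). It held 104 in naive and 121 in antigen-experienced cells and was not called in effector cells. The other 3 shared regions, starting at 52299731, 52314130 and 52318527, also had their highest day 9 mean in low_to_low libraries, at 76.2 ± 1.81, 60.3 ± 1.69 and 46.0 ± 5.05. These means are on the deposited scale, on which the typical region is higher in low_to_low libraries. After centring, the 4 regions differed from low_to_low libraries by log2 fold changes of -0.14 to 0.05, and limma called none of them in any day 9 comparison (adjusted p at least 0.774). A region starting at 52268506 inside the gene was called in both high_to_high libraries (28.7 ± 3.32) and in low_to_high replicates 1 and 3 (31.7 ± 3.04), and in no low_to_low or reference library. The region starting at 52254100, also inside the gene, went the other way. It was called in low_to_low replicates 2 and 3, at 11.6 and 7.73, and in no YFP-high or reference library. A further region inside the gene, starting at 52275491, held 81.6 in naive and 101 in antigen-experienced cells and was called at day 9 only in high_to_high replicate 2, at 17.3. Regions starting at 52261032 and 52261935 were called only in the effector library, at 31.7 and 17.0.

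**Figure D1:**
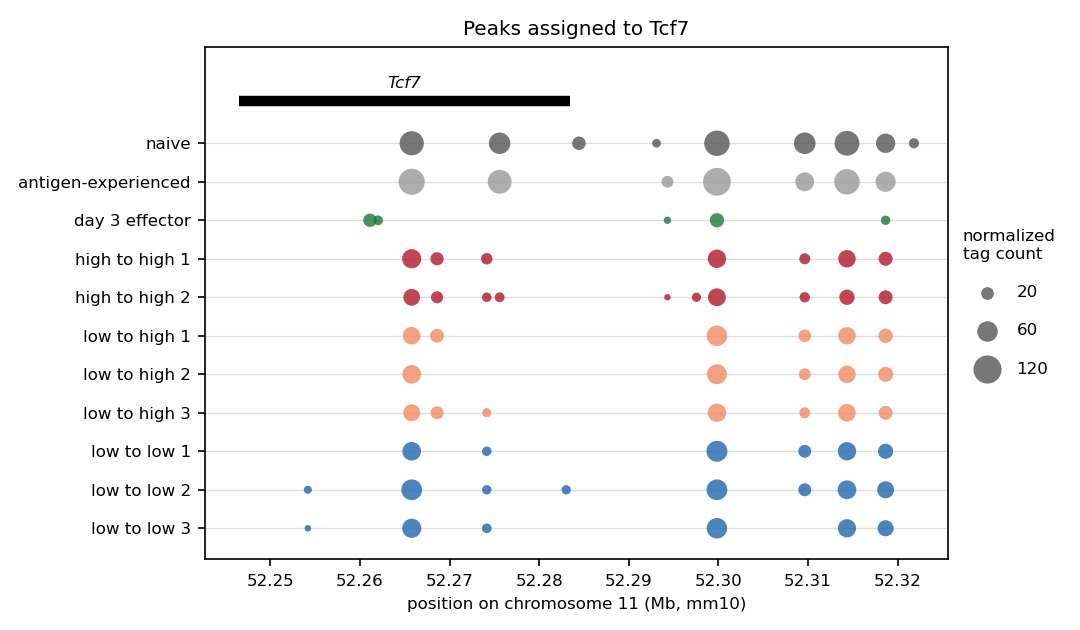
Peaks assigned to Tcf7 in each library, by position on chromosome 11 (Mb, mm10). Circle area is the normalized tag count (tags per 10 M), a missing circle means that no peak was called, and the black bar is the gene span. The region starting at 52268506 appears in 4 of the 5 YFP-high libraries and in none of the 3 low_to_low libraries. The region starting at 52254100 appears only in low_to_low replicates 2 and 3.

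At day 9, 113 regions were more open and 1 was less open in the 5 YFP-high than in the 3 YFP-low libraries. The largest difference lay in Dgkg, a diacylglycerol kinase gene (chromosome 16, 22526376 to 22526688), with a normalized tag count of 12.2 ± 3.37 in YFP-high (SD, n = 5) and 5.16 ± 0.422 in YFP-low libraries (SD, n = 3), a log2 fold change of 1.28 ± 0.19 (SE; limma adjusted p = 0.000348). Regions near Nostrin (chromosome 2, 69125449 to 69125702; 1.19 ± 0.17) and Fabp4, a fatty acid binding protein gene (chromosome 3, 10213047 to 10213418; 1.15 ± 0.20), followed. Regions in Shroom3 (1.09), Evi5 (1.05), Fnip2 (1.03), Ncald (1.00), Aldh1a3 (1.00), St18 (0.99) and Cacna1d (0.99) completed the 10 that the rule names, with limma adjusted p from 0.000303 to 0.0217. The rule takes only regions with a gene and without overlap between the groups, 1 per gene. That each of the 5 YFP-high libraries lay above each of the 3 YFP-low libraries in all 10 is therefore a result of the choice. The 113 regions had a median log2 fold change of 0.77, and 74 of them (65.5%) lay inside a gene span, against 63.7% of all tested regions. The 1 region that was less open lay 12236 bp from Loxl1 (chromosome 9, 58275206 to 58275487), at 22.2 ± 3.00 in YFP-high and 36.7 ± 1.88 in YFP-low libraries, with a log2 fold change of -0.49 ± 0.11 (limma adjusted p = 0.0287). The Loxl1 call was lost with cyclic loess (adjusted p = 0.0607), and those of Loxl1, Fabp4 and St18 were lost on the least favourable omission of 1 library (limma adjusted p 0.128, 0.125 and 0.520). Regions in Aebp2 (-0.41 ± 0.10, adjusted p = 0.0637) and near Slc19a1 (-0.54 ± 0.14, adjusted p = 0.0672) did not pass limma's test, and did with the replicate block (adjusted p = 0.0406 and 0.0390).

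**Figure D2:**
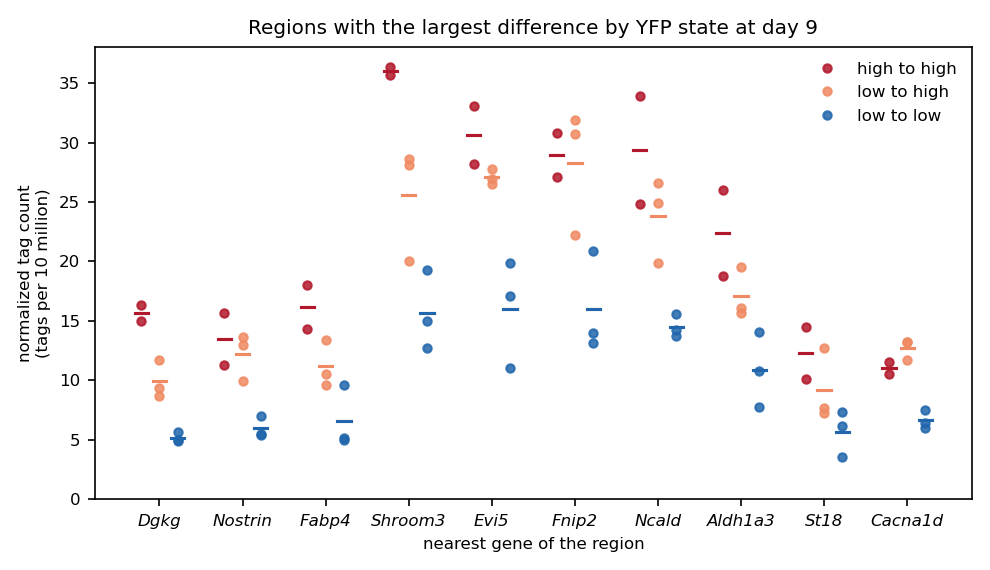
Normalized tag count (tags per 10 M) of the 10 regions with the largest difference by YFP state at day 9, by nearest gene. Points are libraries and bars are group means. The 5 YFP-high libraries average 12.2 at Dgkg and 29.8 at Shroom3, and the 3 low_to_low libraries 5.16 and 15.7.

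These 114 calls came from limma over 34383 regions, where 2776 regions had an unadjusted p under 0.05, 1634 of them higher and 1142 lower in YFP-high libraries. The replicate block gave 213 calls, 207 higher and 6 lower. On the deposited scale without centring, the median region was 0.22 lower (log2) in YFP-high libraries and 2022 regions were called, 79 higher and 1943 lower, so that the excess of more open regions is relative to the typical region. With the share of tags in peaks as a covariate 0 regions were called, and without low_to_low replicate 2, which had the highest share, 16.

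Among the gene lists, 1 of the 173 tested regions of 24 naive and memory genes was more open in YFP-high libraries, 4 when adjusted over the list alone. It lay in Foxp1, a transcription factor gene that helps keep naive T cells quiescent (chromosome 6, 99486292 to 99486538), with 24.0 ± 2.34 in YFP-high and 15.03 ± 5.30 in YFP-low libraries and a log2 fold change of 0.91 ± 0.16 (limma adjusted p = 0.00319). The least favourable omission of 1 library gave 0.66 with a limma adjusted p of 0.170. Of 111 regions of the effector genes, 61 of the inhibitory receptor and exhaustion genes, 84 of the interleukin-2 and activation genes, 51 of the glycolysis genes and 60 of the T cell identity genes, 0 passed limma's test in this comparison. Adjusted over the list alone, 1 region of the interleukin-2 and activation list passed. The list of CD4 and regulatory T cell markers had 1 region more open of 9, 26981 bp from Cd40lg, the gene of CD40 ligand (chromosome X, 57184873 to 57185162; 0.98 ± 0.16, limma adjusted p = 0.00158). It held 10.96 ± 1.98 in YFP-high and 6.04 ± 1.26 in YFP-low libraries. The B cell, myeloid and natural killer lists had 0 calls among 18, 25 and 21 regions, and the erythroid list had 2 regions and was not tested. Camera called 0 lists in the 4 comparisons. Its lowest adjusted p was 0.0839, for the CD4 and regulatory T cell list in low_to_high against low_to_low (0.0695 with the replicate block, 0.0623 with cyclic loess and 0.408 with an estimated correlation).

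The high_to_high libraries had 192 regions more open and 13 less open than the low_to_low libraries. Dgkg led again, at 15.7 ± 0.919 in high_to_high (n = 2) and 5.16 ± 0.422 in low_to_low (n = 3), a log2 fold change of 1.73 ± 0.20 (limma adjusted p = 2.19e-05), followed by Fabp4 (1.52), Shroom3 (1.46), Plch2 (1.42), Nostrin (1.34), Fndc7 (1.32), Nav2 (1.31), St18 (1.31), Aldh1a3 (1.29) and Naa30 (1.28). Among naive and memory genes, regions were more open in Foxp1 (1.10 ± 0.20), 76952 bp from Ikzf2, which encodes Helios (0.97 ± 0.20), and in Bach2, a repressor of effector differentiation (0.61 ± 0.15). Effector genes went both ways. Regions near Tbx21, which encodes T-bet (0.93 ± 0.21), and in Zeb2 (0.90 ± 0.18) were more open, and a region 94331 bp from Id2 (-0.70 ± 0.13) was less open, at 18.5 ± 1.84 in high_to_high and 37.7 ± 3.76 in low_to_low libraries. The region near Cd40lg was more open here too (0.99 ± 0.20). Adjusted over the list alone, 3 regions of the naive and memory list were higher and 1 lower, 4 and 2 of the effector list, and 2 and 0 of the inhibitory list. The less open regions were led by Pald1 (-0.84), BC048562 (-0.73), Id2, Zfp292 (-0.59), Kcnt1 (-0.57), Selenow (-0.57), Tnrc6b (-0.56), Rnf145 (-0.55), Dcps (-0.53) and Aebp2 (-0.52), with limma adjusted p from 0.00301 to 0.0463. Cyclic loess left 6 less open regions and lost Kcnt1, Tnrc6b, Rnf145, Dcps and Aebp2, and the replicate block lost Dcps.

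Limma called these 205 regions in the model of 3 groups, with 3412 regions at an unadjusted p under 0.05, and the replicate block gave 374, 330 higher and 44 lower. On the deposited scale 7410 regions were called, 149 higher and 7261 lower, against a median shift of -0.30. With the share of tags in peaks as a covariate 0 were called, and the 192 more open regions went from a median of 0.93 (SE 0.19) to 0.66 (SE 0.29), all still positive. With the replicate block as well the median was 0.72 (SE 0.54) and 181 of the 192 were positive. Leaving out 1 high_to_high library leaves 1 in that group, and the fit then takes its spread from the other groups. Without high_to_high replicate 1 most calls were lower. The counts were 315 without low_to_low replicate 1 and 70 without low_to_low replicate 2. Of the 26 named regions that were called, 7 passed whichever single library was left out, in Dgkg, Shroom3, Plch2, Fndc7 and Nav2 and near Fabp4 and Naa30.

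Cells that went from low to high had 11 regions more open and 0 less open than cells that stayed low. Nostrin led, at 12.2 ± 1.97 in low_to_high (n = 3) and 5.96 ± 0.914 in low_to_low libraries (n = 3), a log2 fold change of 1.09 ± 0.19 (limma adjusted p = 0.0132). Cacna1d (1.01), Dgkg (0.99), Cd40lg (0.97), Fnip2 (0.96), Evi5 (0.93), Shroom3 (0.84), Ncald (0.84), Eipr1 (0.77) and Gm7244 (0.75) followed, with limma adjusted p from 0.0125 to 0.0430. All 11 were also among the 192 regions more open in high_to_high than in low_to_low libraries. The 2 comparisons share the 3 low_to_low libraries, so that some of this overlap would occur in unchanged groups. The regions with the lowest p among those less open, in Vps8 (-0.47), near Loxl1 (-0.47) and in Asb7 (-0.58), did not pass (limma adjusted p 0.246 to 0.372).

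Limma gave 1910 regions at an unadjusted p under 0.05 for low_to_high against low_to_low. Adjusted over the list alone, 1 region of the naive and memory list was more open. The replicate block gave 55 calls, all higher, and a blocked fit of these 2 groups alone, chosen after seeing the data, gave 118, 113 higher and 5 lower, with Vps8 (adjusted p = 0.0266) and Loxl1 (adjusted p = 0.0398) among the lower ones. No region was called on the deposited scale, where the median region was 0.17 lower (log2) in low_to_high libraries, with the share of tags in peaks as a covariate, or without low_to_low replicate 2, low_to_low replicate 3 or low_to_high replicate 3, while 5 were called without low_to_high replicate 1 and 55 without low_to_low replicate 1. The covariate took the 11 regions from a median of 0.93 (SE 0.16) to 0.62 (SE 0.22), all still positive.

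The 192 regions more open in high_to_high libraries had a median log2 fold change of 0.93 there and of 0.50 in low_to_high, both against low_to_low libraries. Sharing the low_to_low libraries would alone carry 0.93 over to 0.37, by 20 simulations of unchanged groups. These simulations treated the libraries as independent and left out the pairing by replicate number. All 192 regions and the 13 less open ones had the same sign in both comparisons. They were chosen on their difference from the shared libraries, which favours the same sign. The simulations gave no value for regions chosen in this way. Over all 34383 regions 69.5% had the same sign, against 64.6% in the simulations, and the fold changes correlated at 0.612, against 0.447. A check without shared libraries, chosen after this result was seen, took the 192 regions with the largest difference between high_to_high and 1 or 2 of the low_to_low libraries. It measured them in same-numbered low_to_high and low_to_low libraries that the choice had not used. Over the 6 ways to do so the median log2 fold change of low_to_high against low_to_low was 0.30 to 0.46, each above the central 95% of 1000 random sets of like level, which reached at most 0.11. The share of tags in peaks differed between these groups as well.

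**Figure D3:**
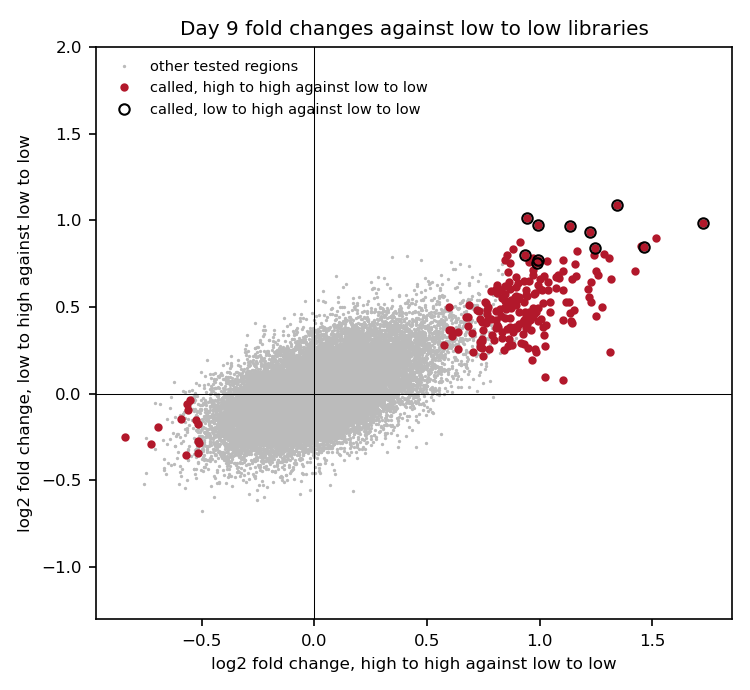
Log2 fold change of each tested region in high_to_high (horizontal axis) and low_to_high (vertical axis) against the same 3 low_to_low libraries. Red points are the 205 regions called for high_to_high, and open circles are the 11 called for low_to_high, all of which are red points at the upper right.

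Between cells of the same day 9 state but opposite day 3 state, 0 regions passed limma's test. In the simulation this comparison called 61.2% of 2-fold and 29.9% of 1.5-fold changes, so differences can have been missed. Among regions with the lowest p, those in Irs2, an insulin receptor substrate gene (-1.02 ± 0.19, adjusted p = 0.246), Nav2 (-1.07 ± 0.22, adjusted p = 0.339) and Fbxl17 (-0.93 ± 0.20, adjusted p = 0.740) had lower values in low_to_high than in high_to_high libraries by limma. Irs2 held 6.92 ± 1.01 in low_to_high (n = 3), 13.7 ± 0.141 in high_to_high (n = 2) and 7.41 ± 0.907 in low_to_low libraries (n = 3). At Nav2 the values were 5.69 ± 0.897, 11.9 ± 0.990 and 5.39 ± 0.985. Regions in Adsl (0.56), Rnf145 (0.52) and Plac8 (0.58) had higher values in low_to_high libraries, each with a limma adjusted p of 0.923. Limma gave 1749 regions at an unadjusted p under 0.05, 907 higher and 842 lower, and voom 2054 with 0 calls. The replicate block called 4 regions, all less open in low_to_high libraries, Irs2 (-1.08) and Nav2 (-1.15) among them, each with a limma adjusted p of 0.0216. This fit pairs high_to_high libraries by number, although they correlated with no number. The deposited scale, on which the median region was 0.13 higher in low_to_high libraries, called 1. Leaving out high_to_high replicate 1 leaves 1 library in that group, with the spread taken from the other groups. The calls of that fit were all higher in low_to_high libraries. The library left, high_to_high replicate 2, has the narrower peak window, whose part in these calls was not tested.

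The test did not show peak lists of the same day 9 group to be more alike than lists of different groups. The mean Jaccard index was 0.743 within groups and 0.737 between them, a difference of 0.00542 (one-sided exact permutation test over 280 regroupings, p = 0.264). The regroupings do not keep same-numbered libraries together, and the pair of low_to_low and low_to_high replicates 1 had the highest index of all day 9 pairs, 0.795, which raises the mean between groups. The index averaged 0.754 ± 0.0209 between low_to_high libraries (SD, 3 pairs), 0.749 ± 0.0285 between low_to_low libraries (3 pairs) and 0.749 ± 0.0293 between the low_to_high and low_to_low groups (9 pairs). It was 0.690 for the pair of high_to_high libraries. With the naive library the index averaged 0.602 ± 0.0225 for high_to_high, 0.592 ± 0.0178 for low_to_high and 0.590 ± 0.0181 for low_to_low, and with the effector library 0.387 ± 0.0110, 0.385 ± 0.0108 and 0.392 ± 0.0109. With equal numbers of strongest peaks the within-group excess was 0.0113 (exact permutation p = 0.0357), and without low_to_high replicate 3 it was -0.00189.

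**Figure D4:**
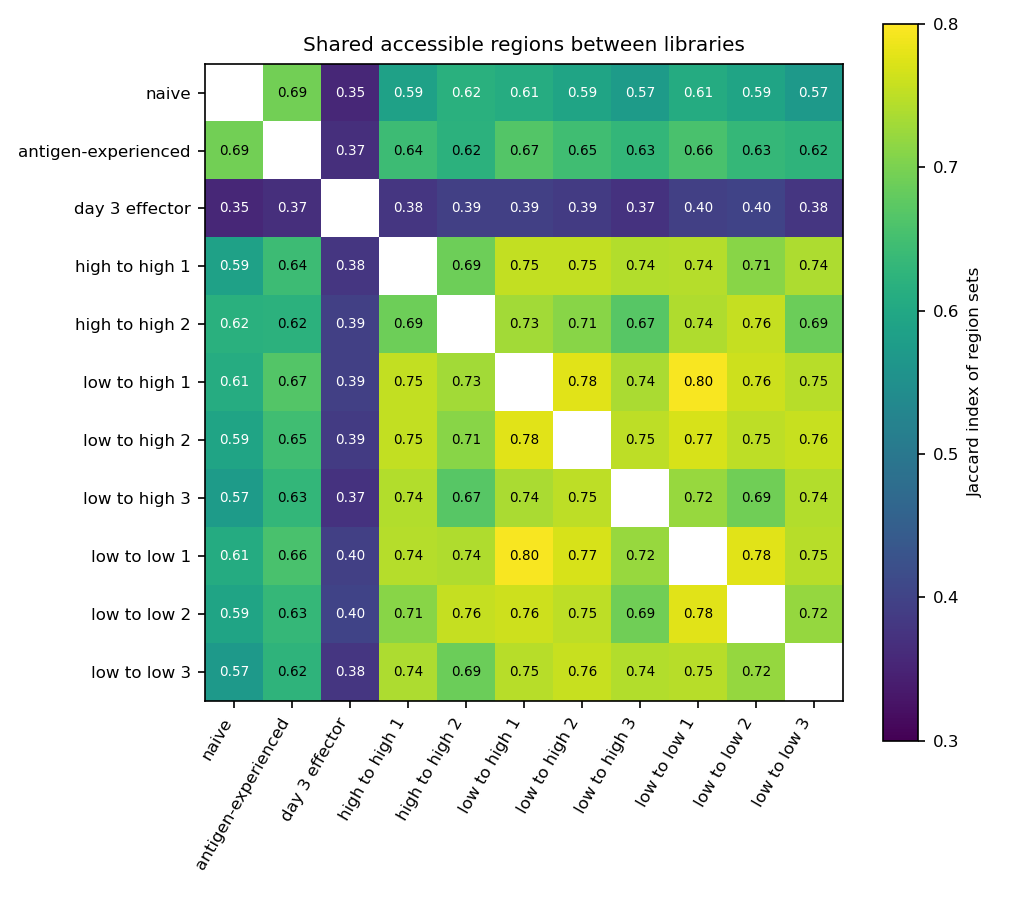
Jaccard index of the region sets of each pair of the 11 libraries, from dark (few shared regions) to light (many). The effector library shares few regions with any other, with an index of 0.355 with naive cells, and the 8 day 9 libraries form 1 block without a boundary between YFP states.

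Peaks present in every library of 1 YFP state and absent from the other were few. In all, 47 regions were called in each of the 5 YFP-high and in none of the 3 YFP-low libraries, and 77 the other way round. Of the 56 splits of the 8 libraries into 5 and 3, 26 gave at least 47 and 21 gave at least 77, so neither count stood out from these splits, which also part same-numbered libraries in different ways. The strongest of the YFP-high regions lay near Ostc (chromosome 3, 130709476 to 130709797), with a normalized tag count of 44.7 ± 11.7 (SD, n = 5), near Dyrk3 (32.5 ± 0.963), in Herc6 (24.3 ± 2.26), in Gpr55 (23.6 ± 2.86) and in Nr3c1, the glucocorticoid receptor gene (22.8 ± 1.81). Prkca, Fam71b, Mfsd2a, Nt5c and E2f7 followed, with means of 22.0 down to 19.7. Among the YFP-low regions D16Ertd472e (35.0 ± 3.68, n = 3), Cblb, a ubiquitin ligase gene that restrains T cell activation (22.1 ± 1.99), and F2rl2 (18.8 ± 2.96) came first. Cdc25b, Cdc14a, Lpgat1, Psrc1, Map3k8, Nt5c3b and Supt6 had means of 15.5 down to 11.5. A missing peak means only that the region was not called.

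The share of regions called in the naive and not in the effector library gave no difference that passed a test between day 9 groups. Of the 25065 such regions, high_to_high libraries called 52.6 ± 11.1% (SD, n = 2), low_to_high 44.7 ± 1.95% (n = 3) and low_to_low 47.3 ± 3.76% (n = 3). The antigen-experienced library called 59.1%. The YFP-high libraries lay 0.541 percentage points above the YFP-low libraries (two-sided exact permutation test, p = 0.964). Low_to_high lay at -2.64 points from low_to_low (exact permutation p = 0.3) and at -7.96 points from high_to_high (exact permutation p = 0.2), where 0.1 is the smallest p that these group sizes allow. The splits take no account of same-numbered low_to_low and low_to_high libraries. The first difference was 0.855 with equal numbers of strongest peaks, and the second ran from -15.8 without high_to_high replicate 1 to -0.102 without replicate 2. The sign of the YFP difference rested on high_to_high replicate 2, which called 60.5%, since without it the difference was -2.62 points, and it was -1.54 points without low_to_low replicate 3.

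Of the 33711 regions called in the effector and not in the naive library, high_to_high libraries called 13.9 ± 4.51% (n = 2), low_to_high 10.9 ± 0.754% (n = 3) and low_to_low 13.3 ± 2.27% (n = 3), against 5.88% in the antigen-experienced library. The YFP-high libraries lay at -1.20 points from the YFP-low libraries (two-sided exact permutation test, p = 0.536), with -2.45 points (exact permutation p = 0.0286) without high_to_high replicate 2 and 0.0626 points without low_to_low replicate 2. Low_to_high lay at -2.40 points from low_to_low, with every low_to_high library below every low_to_low library, which gives the smallest exact permutation p possible, 0.1, and comes up in 2 of 20 splits by chance. These splits take no account of same-numbered libraries. With equal numbers of strongest peaks the difference was -0.480 points (exact permutation p = 0.3). It lay at -2.99 points from high_to_high (exact permutation p = 0.3), with 0.674 points for equal numbers of strongest peaks and 0.199 without high_to_high replicate 2.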

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

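Of 20 values tested in the 5 YFP-high libraries, 4 had 1 library far from the others, where chance gives about 1 in 20, and 3 of the 4 belong to high_to_high replicate 2. It had 62581 peaks, against 46454 to 49744 in the other 4. It called 60.5% of the naive-only regions, against 42.7 to 46.6%, and 17.1% of the effector-only regions, against 10.1 to 11.4%. High_to_high replicate 1 held 33.1 tags per 10 M in the Evi5 region, against 26.5 to 28.2 in the others. The Y chromosome, which no comparison uses, carried 12 to 19 peaks per library.

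For the high share of naive-only regions in high_to_high replicate 2, 2 technical explanations were tested, both stated before their results were seen. The library was the deepest, and a longer list from deeper sequencing as the whole cause is argued against by equal numbers of strongest peaks, where its share was 59.1% and the highest of the other 7 day 9 libraries 56.6%, although the gap shrank. Its peak window was narrower than in the other day 9 libraries and close to that of the naive library. With equal numbers of peaks its Jaccard index with the naive list exceeded the mean of the other 7 libraries by 0.0345. With the antigen-experienced list the excess was -0.00925, a difference of 0.0437. This met the prediction for the peak window, which may account for part of the share. A library nearer to naive cells would give the same difference, so the value cannot tell the 2 apart. No biological explanation was tested, and high_to_high replicate 1 called 44.8%.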

How the results depend on the processing

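The share of tags in peaks, voom, the blocked fit of low_to_high and low_to_low alone, the block with the share of tags in peaks, cyclic loess for the gene lists and the 1 kb gene-end regions were tried after the data were seen. The 83 alternatives of the comparisons, left-out libraries aside, left 57 values in the same direction, on the same side of the threshold and, for counts, within 1.5 times. Some of these could hardly change. Values per kb divide by a peak width that is fixed within a library, which centring removes again apart from the pseudocount. They do not test the narrower window of high_to_high replicate 2. Permutation tests of low_to_high against 1 other group cannot give a p under 0.1, so they could change only in sign. Gene lists stayed at 0 calls throughout. On the deposited scale, YFP-high against YFP-low called 2022 regions (79 higher), high_to_high against low_to_low 7410 (149 higher), low_to_high against low_to_low 0, and low_to_high against high_to_high 1. On that scale the median region shifts by -0.22, -0.30, -0.17 and 0.13. With regions called in at least 3 libraries, 56285 regions were tested with missing values filled in. The counts were 39 (31 higher, 8 lower), 30 (17 higher, 13 lower), 53 (23 higher, 30 lower) and 33. Only 1, 0, 0 and 0 of these are among the calls of the report, so that nearly all calls were lost. Regions called in all 8 day 9 libraries kept their fold changes in this fit, while the error and the number of tests changed. A pseudocount of 10 gave 184 for YFP-high against YFP-low and 333 for high_to_high against low_to_low, and the mean of both high groups 191 for the former; the cause was not tested. The share of tags in peaks as a covariate, with or without the replicate block, gave 0 in the 3 comparisons that had calls.

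The replicate block gave 213, 55, 374 and 4 calls in the order of the report's YFP, low_to_high against low_to_low, high_to_high against low_to_low and low_to_high against high_to_high comparisons, and 118 for low_to_high and low_to_low alone. The block changed no gene list call. It also covers the high_to_high libraries, which correlated with no number.

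Leaving out 1 library gave 16 to 203 calls for YFP-high against YFP-low, 0 to 55 for low_to_high against low_to_low, 70 to 315 for high_to_high against low_to_low (124, mostly lower, without high_to_high replicate 1) and 0 to 11 for low_to_high against high_to_high. The within-group excess in similarity ran from -0.00189 (without low_to_high replicate 3) to 0.0157, and was 0.0113 with equal numbers of peaks (exact permutation p = 0.0357). Regions in every YFP-high and no YFP-low library numbered 55 to 175, and the reverse 105 to 468. Leaving out a library removes a condition, so these counts cannot fall below the 47 and 77 of all libraries. With peaks above their list's median the first count was 28. The naive-only difference ran from -2.62 to 2.11 points (negative also without low_to_low replicate 3, -1.54), and the effector-only difference from -2.45 to 0.0626, its only positive value. Low_to_high minus low_to_low ran from -4.72 to -1.07 for naive-only and -3.33 to -1.13 for effector-only regions, and low_to_high minus high_to_high from -15.8 to -0.102 and from -6.18 to 0.199, positive without high_to_high replicate 2. With equal numbers of peaks the naive-only difference of low_to_high from low_to_low was 0.855, and the effector-only difference from high_to_high 0.674. The cause of the other changes was not tested.

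None of the 711 alternative values of the named regions changed sign. Most of these regions were chosen for a large fold change without overlap between groups, or for a low p, which favours a stable sign. The values kept their side of the threshold in 532 and lost a call in 167. Of the 49 called, 0 stayed with the share of tags in peaks as a covariate, 1 with regions called in at least 3 libraries and 16 whichever library was left out. Depth limits all peak lists, since a region under 16 to 28 read ends is not listed. The filter on local signal, which removed 36.4 to 53.3% of putative peaks, can leave out stronger regions too. The count models, the regions within 1 kb of a transcription start and the motif alternatives were not run, for lack of whole reads, strand and genome sequence.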

Other observations

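The tests of library splits, of a level trend, of the references of the YFP-high regions, of the region sets and of B cells were chosen after the results they bear on were seen. Regions called in the effector library and in neither splenocyte library were counted per gene, which favours genes with long spans. Lpp carried 50 such regions, Sox5 46, Pde4d 42, Inpp4b 39 and Rad51b 36, and the naive and memory list had 149 such regions in 22 of its 24 genes, above all 10000 random lists of genes of like span. The effector list had 101 (also above all of them), the interleukin-2 and activation list 67, the T cell identity list 72, the inhibitory list 64 and the natural killer list 16 (98.6th percentile). Glycolysis genes had 15 (31.6th percentile), the CD4 and regulatory list 6, the myeloid list 21, the erythroid list 3 and the B cell list 30 (92.7th percentile). Random lists were drawn from all protein-coding genes, matched on span and not on activity in T cells. A high rank therefore need not be particular to the genes of a list. Regions of the opposite kind, called in both splenocyte libraries and not in the effector library, numbered 127 for the naive and memory list, 80 for T cell identity and 55 each for the effector and the interleukin-2 and activation lists, without a test.

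The 113 regions more open in YFP-high libraries were often without a peak in the effector library, where 46.9% had one, against 71.8% on average in 10000 random sets matched on level (63.7 to 79.6% in the central 95 of 100). Both splenocyte libraries had a peak in 89.4%, against 84.9% (77.9 to 91.2%). A hypothesis is that these are regions that close on activation and that were open in naive and antigen-experienced cells. The effector value meets what it requires and the splenocyte value does not exceed the random range, while 50.4% had both splenocyte peaks and no effector peak, against 21.1% (14.2 to 29.2%). Since the low effector share alone raises this value, the hypothesis stays open. Of 6 region sets tested with camera in this comparison, the 6795 regions with a naive and no effector peak had a median log2 fold change of 0.02 (adjusted p = 0.0925, or 0.175 with an estimated correlation), and the 1242 at least 2-fold lower in effector than in naive cells 0.02 (adjusted p = 0.0290, or 0.611). The 186 regions at least 2-fold lower in antigen-experienced than in naive cells had 0.10 (adjusted p = 1.84e-05, or 0.175), so no set was called with an estimated correlation. Cyclic loess gave the 3 sets medians of 0.01, 0.05 and 0.07 (adjusted p 0.236, 7.88e-05 and 0.00108).

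The excess of more open regions in YFP-high libraries was weighed against 3 explanations. The limit to regions called in all 8 day 9 libraries was not among them. With regions called in at least 3 libraries and missing values filled in, 31 were called higher and 8 lower. Of the 56 splits of the 8 libraries into 5 and 3, only 1, the real one, called as many as 114 regions, and the highest other called 77 (low_to_low replicates 2 and 3 with low_to_high replicate 2), but only 8 of these splits put 1 library of each same-numbered pair on each side, with 0 calls in the other 7. A share of 1 in 8 cannot fall under 0.05, so chance stays open where the numbers pair libraries. For low_to_high against low_to_low 1 of 10 splits, the real one, called 11 and the highest other 0, also in the 3 others that part all same-numbered pairs, but 10 splits are too few for a share under 0.05. A trend of the fold change with level is argued against by cyclic loess, which left 103 regions higher and 0 lower. The lower share of tags in peaks of every YFP-high library cannot be told apart from YFP state: in 100 regions chosen without the 2 libraries compared, the difference at an equal share was 0.27 ± 0.25 (jackknife SE; 0.08 to 0.41 with 1 library left out). All 15 high and low pairs were positive (up to 0.83), but the pair closest in share, low_to_high replicate 2 and low_to_low replicate 1, gave only 0.09, with 62% of regions positive. The choice for this pair kept their same-numbered partners, on opposite sides. Its value, and with it the difference at an equal share, is therefore not free of the pairing. In the full fit the covariate moved the median fold change of the 113 regions from 0.77 (SE 0.16) to 0.46 (SE 0.25), and together with the replicate block to 0.29 (SE 0.38) with 93 positive, so that calls ended through a smaller fold and a wider error. A biological effect of YFP state therefore stays open and could not be separated from it.

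In the effector library Ebf1, a B cell transcription factor gene (chromosome 11, 44618100 to 45008096), carried 28 regions, against 5 in naive, 7 in antigen-experienced and 8 to 10 in day 9 libraries, with values up to 28.8 tags per 10 M. B cells in the library could bring such peaks. The other 9 genes of the B cell list, however, had 5 effector-only regions (14.1th percentile of random lists of genes of like span). Cd79a and Cd79b had 0 effector peaks, but Cd79a had 0 in every library and so tells nothing. Pax5 had 7 effector regions (up to 19.2), against 4 in naive, 7 in antigen-experienced and 3 to 9 in day 9 libraries. Ms4a1 had 1 effector region (3.38) and 0 in every other library. The whole B cell list, Ebf1 included, was 0.87 higher in effector than in naive cells over regions called in both. B cells are therefore not excluded. Stromal cells in the culture could also open Ebf1, but a list of 20 stromal genes had 22 effector-only regions in 9 genes (9.32th percentile), Col1a1 and Fn1 had 1 effector region each (22.9 and 5.92), and Col1a2 and Col3a1 had 0. Counts per gene favour long spans, and Ebf1 was not among the 15 genes with the most effector-only regions, which carried 28 to 50 each. The labels give CD8 T cells as the cell type and name no sort for this library. No biological explanation was tested, and the library has no replicate.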
